A study of Mus musculus with 4 samples.

How the data were processed

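RNA of the mouse pre-osteoblastic line MC3T3-E1 (a skull-derived line that can mature into osteoblasts) was sequenced in 4 libraries, 1 per group. The groups were an untreated control, cells under tensile strain, cells in medium conditioned by PC-3 cells (a human prostate cancer line), and cells given both. Per the labels, strain was 2500 microstrain at 0.5 Hz for 1 h per day, RNA was extracted with Trizol, and libraries were made with a directional NEBNext Ultra kit. How long the treatments lasted, when cells were harvested relative to the last bout of strain, and any batch of culture or sequencing are not given in the sources used here. With 1 library per group, a batch and a treatment cannot be told apart. No group had medium conditioned by other cells, so effects particular to PC-3 cells cannot be told apart from those of conditioned medium generally.

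The values came from a single table of 41288 genes, of which 21873 were annotated as protein-coding and 11591 as lncRNA. Per the file headers, the authors deposited a whole-number read count and an RPKM value (reads scaled to the length of the gene model and to the library's total) for each gene and library. Per the submitters' processing notes, reads were aligned with HISAT2, with no version stated, and the notes name the build mm9. The table's own positions are those of a later build: 28744 of the 40033 genes matched by Entrez number (71.8%) had the same chromosome and start as in a GRCm38.p6 RefSeq gene table. Coordinates in the report are printed as the table gives them and are read as GRCm38. The counting tool, its strand setting, its treatment of reads that fit several genes and the annotation version are not given in the sources used here. Counts of near-identical copies (Saa3, Ly6c1, histone and osteocalcin genes, Hmga1) are uncertain for that reason, as are genes with an expressed partner on the opposite strand, among the named genes Timp1, Fosl1, Ampd3, Car9, Dusp6 and Ifi27l2a. The RPKM values that the authors deposited were recomputed as the count divided by gene length and by the library's own count total, and differed from the deposited values by a relative 5.05e-06 at most.

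The table names its columns only L, T, LT and O. LT was read as the library with both treatments and O as the control, because LT joins the other single-letter names and O shares no letter with them. L was read as loading, a word that only the strained samples' titles hold, and T as conditioned medium by elimination. The labels do not spell out T. If it stood for tensile, the strain and conditioned-medium libraries would exchange places in every comparison except that of both treatments against control. No expression value was used to assign a column.

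Depth was 10997085 counts in the control library, 10722179 in the strain library, 10659166 in the conditioned-medium library and 10007546 in the library with both. At that depth 3 counts in a gene model of 1 kb gave 0.273 to 0.300 RPKM. Between 12234 and 12391 genes per library had at least 1 RPKM.

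The design planned for either deposited unit, and with normalized values present the main measure was the difference of log2(RPKM + 1) between libraries, a scale that understates the change of genes with low values. With 1 library per group there are no replicates to test within a comparison. An additive model of both treatments over the 4 libraries, whose 1 residual degree of freedom would hold any joint effect of the treatments as well as error, was not run. No p-value was computed, and genes were selected by size alone: a log2 ratio of at least 1 either way, with the higher of the RPKM values at least 1. Beside it, the ratio of count shares is given as a fold with a 95% interval derived from the exact Clopper-Pearson interval of a gene's counts in the first library out of its counts in both. These intervals cover counting error only, not differences between cultures, and reads copied in PCR are not independent molecules. To show how many genes sampling of reads alone brings past the size rule, each gene's pooled counts were divided at random between the libraries in proportion to their totals, in 100 draws.

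The comparisons were strain against control, conditioned medium against control, conditioned medium plus strain against strain, and conditioned medium plus strain against conditioned medium. A further comparison, conditioned medium plus strain against control, was added after seeing the data because it does not depend on how L and T are read. Across genes, the strain responses with and without conditioned medium were compared by Pearson's r and Spearman's rho over genes with a mean RPKM of at least 1, and likewise the conditioned-medium responses; the members of each such pair have no library in common. Gene lists were fixed before the data were examined, along with the size rule, the alternative settings and the rule for named genes. For each list with at least 5 members at a mean RPKM of at least 1, the median log2 ratio was set among 10000 random lists of the same size matched on deciles of mean expression, and a median outside the 2.5th to 97.5th percentile was said to stand apart. This describes these libraries only: members of a coregulated list vary together, so such lists leave the band more often than the 5% of independent genes.

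Named genes were chosen per comparison. Symbols of predicted genes, pseudogenes and small RNAs (microRNA, small nucleolar or small nuclear RNA) were left out. Up to 10 genes with the highest and 10 with the lowest log2 ratio were taken, if they met the size rule at 5 RPKM or more. To these came up to 4 members of each list that met the size rule, the 9 osteoblast genes Runx2, Sp7, Alpl, Col1a1, Bglap, Ibsp, Spp1, Tnfsf11 and Tnfrsf11b whatever their values, and, for the difference between the strain responses, the 5 highest and 5 lowest. Genes outside this rule are said to have been chosen after their values were seen.

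The procedure was tested on simulated data with known answers, Poisson counts of all 41288 genes at the real depths with 50 genes changed at each fold and direction. Rates were those of the control library, in which 21443 genes had a count. Genes without a count there could not pass the size rule, unlike in the random division of pooled counts. In every simulated comparison 98% to 100% of genes changed 3-fold or 6-fold were recovered, and 120 to 146 unchanged genes also passed the size rule. The fold intervals held the true value in 95.1% to 95.4% of genes. The changed genes, and those whose intervals were checked, had at least 5 RPKM in the control. Recovery and intervals of genes with lower values were not tested. Alternatives covered the pseudocount (0.1 and 5 in place of 1), the filter on low values, and the expression minimum for correlations and lists. They also covered the scaling (median-of-ratios factors on RPKM, and TMM-scaled CPM from the counts), and predicted-gene, pseudogene and small RNA names left out. A minimum of 30 counts in the higher library, correlations without the immediate early genes and 3 genes with ribosomal RNA-like signal, and library totals without those 3 genes, were added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors alone.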

Results

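Transcript levels were measured by RNA sequencing in MC3T3-E1 mouse pre-osteoblasts that were left untreated, subjected to tensile strain, kept in medium conditioned by PC-3 prostate cancer cells, or given both. Each group was 1 library of 10007546 to 10997085 counts, so every difference described here lies between single libraries and has no replicate check. Values are RPKM, folds are ratios of count shares, and the bracketed 95% intervals cover counting error only. Which single-letter column is strain and which is conditioned medium was read from the sample titles and is not spelled out in them; under the opposite reading, statements on strain and on conditioned medium would exchange.

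The comparison of conditioned medium plus strain against strain addresses the question in the series title, how the cancer cells' medium alters transcript levels in strained osteoblasts. Lcn2 (lipocalin 2, an iron-siderophore-binding protein) had 30.9 RPKM against 1.86 in the strain library, a fold of 16.6 (10.2 to 29.0), and Hp (haptoglobin) 16.1 against 1.04, a fold of 15.5 (9.19 to 28.2). Mmp13, which encodes the collagen-degrading enzyme collagenase 3, had 89.2 against 7.43, a fold of 12 (10.4 to 13.9). Dmp1, a matrix protein gene of osteocytes, was 7.80-fold lower (6.63 to 9.22), at 5.29 against 41.2 RPKM.

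Among the other genes with the highest ratios in that comparison, Saa3 (serum amyloid A3) was 7.39-fold higher (6.06 to 9.10), the potassium channel gene Kcnj15 5.53-fold (4.80 to 6.38) and Nos2, the inducible nitric oxide synthase, 5.83-fold (4.45 to 7.73). Angptl4, Il4ra, Gfra1 and Il6 were 3.83-fold to 3.99-fold higher. On the other side stood Otor, 5.08-fold lower (3.58 to 7.39), Fosb, 3.18-fold lower (2.90 to 3.49), Egr3, 3.17-fold lower (2.52 to 4.01), Megf10, 3.07-fold lower (2.61 to 3.63), and Dusp6, 2.5-fold lower (2.32 to 2.70). In GRCm38 positions, Lcn2 lies on chromosome 2 at 32384637 to 32387739, Mmp13 on chromosome 9 at 7272514 to 7283333, Dmp1 on chromosome 5 at 104197558 to 104214109 and Otor on chromosome 2 at 143078492 to 143081700.

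Of the gene lists, cell cycle genes differed most in that comparison: all 38 expressed members had lower values with conditioned medium plus strain than with strain, with a median log2 ratio of -0.77, below all random lists, and 6 met the size rule. Ccnb2 (cyclin B2) was 2.71-fold lower (2.17 to 3.39), Ube2c 2.67-fold (2.25 to 3.17), Plk1 2.31-fold (1.94 to 2.75) and Aurkb 2.23-fold (1.86 to 2.69). The mitotic phosphatase gene Cdc25c, outside the list, was 3.06-fold lower (2.35 to 4.02). All 28 expressed hypoxia and glycolysis genes had higher values, with a median of 0.46, and 3 met the size rule: Pfkfb3 was 2.74-fold higher (2.47 to 3.05), Bnip3 2.44-fold (2.16 to 2.77) and Car9, a carbonic anhydrase gene, 2.97-fold (2.0 to 4.5). Of 24 sterol synthesis genes 23 had lower values, with a median of -0.37, and none met the size rule. In the inflammatory and NF-kappaB list 15 of 21 members were above 0, with a median of 0.18, and 5 met the size rule upward. The immediate early list (median -0.46), the interferon list (-0.29), the TGF-beta list (-0.23), the p53 list (-0.23), the cytoskeletal list (-0.16), fatty acid synthesis and lipid storage (-0.13) and ribosomal proteins (-0.11) also lay below the random band. Collagen processing enzymes (0.13), matrix proteases (0.12), the fixed long non-coding RNAs (0.10) and the amino acid stress response (0.08) lay above it.

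By the size rule 175 genes were higher and 171 lower with conditioned medium plus strain than with strain, out of 12621 with at least 1 RPKM in either library. Sampling of reads alone brought 212 genes past the rule on average and 238 at most. With at least 30 counts in the higher library, a minimum chosen after seeing the data, 53 genes were higher and 35 lower, where sampling gave 0.36 on average and 3 at most.

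Conditioned medium against control addresses the effect of the medium without strain. Mmp13 had 91.3 RPKM in the conditioned-medium library and 5.47 in the control, a fold of 16.7 (14.2 to 19.7). Hp was 13.7-fold higher (7.97 to 25.6), Lcn2 13.2-fold (8.34 to 21.9), Kcnj15 8.98-fold (7.62 to 10.6) and Saa3 7.23-fold (5.90 to 8.93). Spp1 (osteopontin), already among the most abundant transcripts at 1223 RPKM in the control, stood at 3455, a fold of 2.82 (2.78 to 2.87), while Postn (periostin) was 2.26-fold lower (2.24 to 2.28), at 2095 against 4735. Otor was 8.72-fold lower (6.14 to 12.8) and S100b 3.84-fold lower (3.31 to 4.46).

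In the same comparison Il4ra (the interleukin 4 receptor chain) was 5.77-fold higher (5.05 to 6.61), Nos2 5.94-fold (4.55 to 7.85) and Il6 4.70-fold (3.45 to 6.52). Osmr and Il6st, receptor chains for oncostatin M and the interleukin 6 family, were chosen after their values were seen and were 3.89-fold (3.67 to 4.13) and 2.24-fold (2.14 to 2.34) higher. The metal-binding protein genes Mt2 and Mt1 were 4.32-fold (4.03 to 4.63) and 2.36-fold (2.18 to 2.55) higher, Hmox1 (heme oxygenase 1) 2.21-fold (2.11 to 2.31), the protease inhibitor gene Timp1 3.13-fold (2.83 to 3.46) and Mmp3 6.42-fold (3.15 to 14.8), the last on 56 and 9 counts. Angptl4 was 5.02-fold higher (4.45 to 5.68), Ampd3 4.44-fold (4.02 to 4.91), Wisp2 3.78-fold (3.55 to 4.03) and the AP-1 gene Fosl1 3.0-fold (2.73 to 3.31).

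Interferon-response genes were lower in the conditioned-medium library than in the control in 33 of 38 expressed members, with a median log2 ratio of -0.61 below all random lists. Of these, 7 met the size rule, among them Ifit1, 3.05-fold lower (2.70 to 3.47), Oasl2, 2.85-fold lower (2.46 to 3.33), and Irf7, 3.18-fold lower (2.30 to 4.48). Cell cycle genes had lower values in 36 of 38 members (median -0.48) and sterol synthesis genes in 23 of 24 (median -0.44). Hypoxia and glycolysis genes had higher values in 26 of 28 (median 0.52), with Car9 at 4.57-fold (3.01 to 7.15), Pfkfb3 at 2.75-fold (2.47 to 3.06) and Bnip3 at 2.59-fold (2.30 to 2.92). Matrix proteases and inhibitors (0.37), inflammatory genes (0.30), the amino acid stress response (0.26), YAP and TEAD targets (0.20), the fixed long non-coding RNAs (0.17), collagen processing enzymes (0.14), the BMP response (0.14), oxidative stress and metallothioneins (0.10) and the TGF-beta response (0.09) also stood above the band, as did 7 histone genes (0.52), mostly on few counts. Immediate early genes (-0.39), the cytoskeletal list (-0.15) and fatty acid synthesis and lipid storage (-0.13) stood below it, as did 5 skeletal muscle markers (-0.40), a value that turned to 0.91 with only members at a mean of 5 RPKM or more.

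The size rule was met by 180 genes upward and 161 downward, against 200.91 in both directions from sampling of reads alone and 221 at most. With at least 30 counts it was met by 80 and 32, against 0.37 on average and 3 at most. On TMM-scaled CPM it was met by 135 and 55, so that 71.1% of genes lay upward in place of 52.8%. There the minimum and the pseudocount apply to CPM, without gene length, so that different genes enter.

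**Figure D1:**
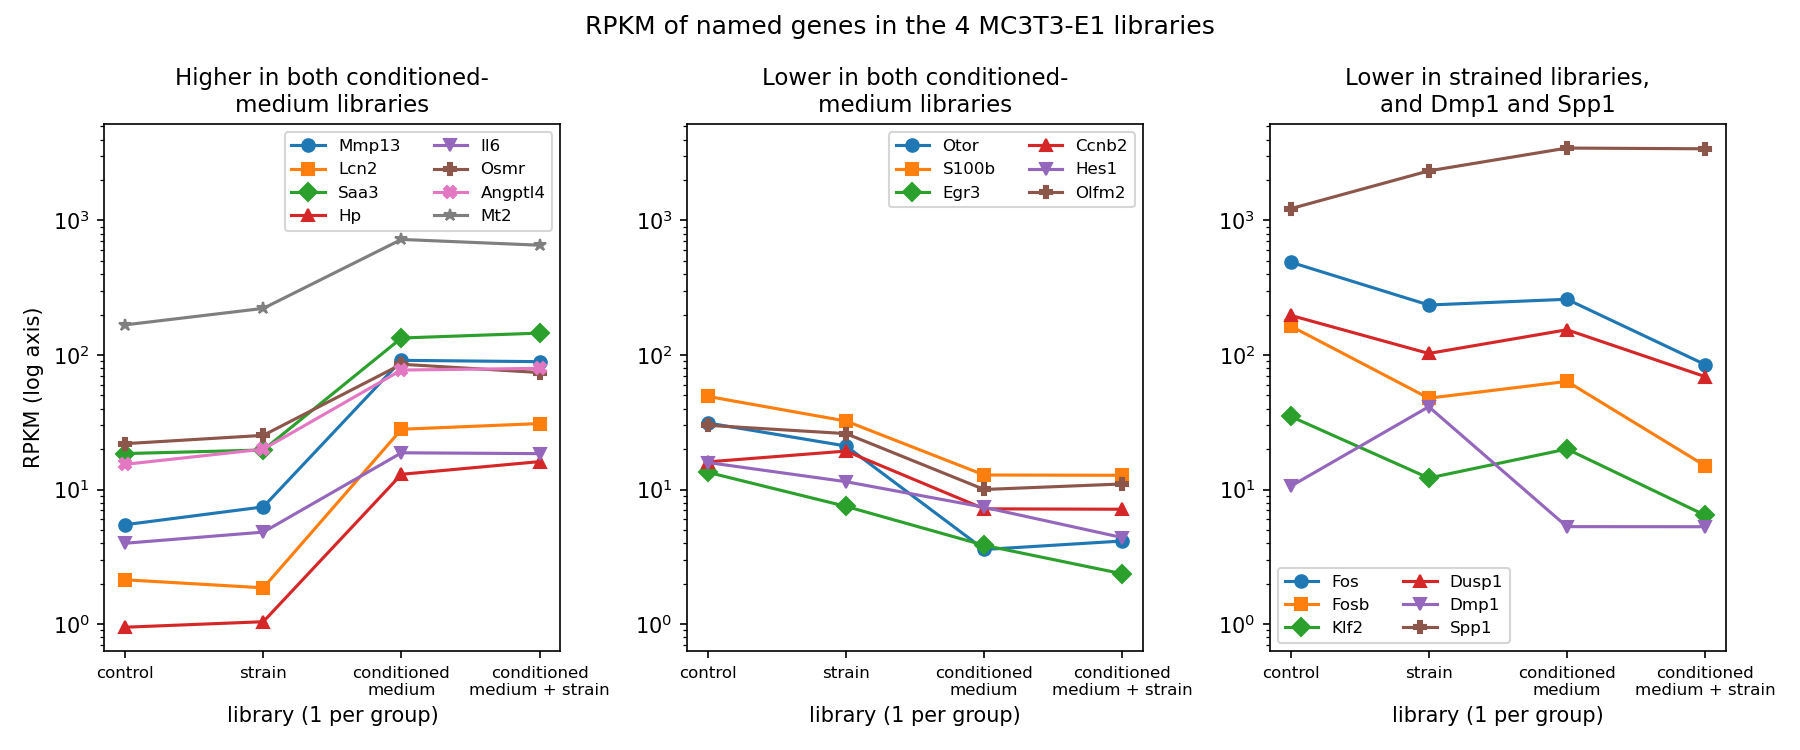
RPKM on a log axis in each of the 4 libraries, 1 point per library and no error bars, for genes higher in both conditioned-medium libraries (left), lower in both (middle), and for immediate early genes with Dmp1 and Spp1 (right); Osmr was chosen after its values were seen. Mmp13 lies at 5.47 and 7.43 RPKM without conditioned medium and at 91.3 and 89.2 with it, while Dmp1 is highest, at 41.2, in the strain library.

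Strain against control addresses the effect of strain in ordinary medium. Dmp1 was 3.91-fold higher in the strain library (3.48 to 4.40), at 41.2 against 10.6 RPKM, and Il1rl1, the interleukin 33 receptor gene, 2.65-fold higher (2.38 to 2.97). Fosb, Klf2, Nr4a1 and Fos, transcription factor genes of the immediate early list, were lower: Fosb by a factor of 3.44 (3.27 to 3.62), Klf2 2.87 (2.47 to 3.34), Nr4a1 2.25 (2.07 to 2.44) and Fos 2.08 (2.02 to 2.15), with Fos at 235 against 490 RPKM. Spp1, at 2338 against 1223 RPKM, was 1.91-fold higher (1.88 to 1.94) and stayed under the size rule.

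Hmga1 was 2.23-fold higher with strain (1.81 to 2.77) and Anxa8 2.14-fold (1.81 to 2.55). Rpph1 and Rmrp, the RNA parts of ribonucleases P and MRP, had folds of 9.23 (2.84 to 47.5) and 4.62 (1.52 to 18.7), on 27 and 18 counts in the strain library against 3 and 4. The cartilage collagen gene Col2a1 was 3.64-fold higher (2.57 to 5.25), on 149 counts against 42. All 38 expressed cell cycle genes had higher values with strain, with a median log2 ratio of 0.29 above all random lists, and none met the size rule. Histone genes (0.67, 7 members), the TGF-beta list (0.23), osteoblast differentiation and mineralization (0.18), p53 targets (0.14), collagens and fibrous matrix (0.12), matrix proteases (0.11), oxidative stress (0.11), ribosomal proteins (0.09), YAP and TEAD targets (0.08), the amino acid stress response (0.08) and collagen processing enzymes (0.05) also lay above the random band. Immediate early genes lay below it, with 21 of 26 members lower and a median of -0.33, as did interferon genes, with 35 of 38 lower and a median of -0.30.

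For strain against control the size rule gave 104 genes higher and 139 lower, 243 in all, where sampling of reads alone gave 203.86 on average and 228 at most. With at least 30 counts, 9 genes were higher and 5 lower (Fos, Fosb, Klf2, Nr4a1 and Gm14327, the last chosen after its values were seen and overlapping Zfp972 on the opposite strand), against 0.4 on average and 3 at most, and on TMM-scaled CPM 31 and 16, with 66.0% upward in place of 42.8%.

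Conditioned medium plus strain against conditioned medium addresses strain in the cancer cells' medium. Here the immediate early genes made up most of the named difference: Fosb was 4.24-fold lower (3.88 to 4.64) in the library with both treatments, Klf2 3.11-fold (2.52 to 3.85), Fos 3.06-fold (2.90 to 3.23) and Dusp1, a MAP kinase phosphatase gene, 2.23-fold (2.09 to 2.38). In the list 25 of 26 expressed members had lower values, with a median of -0.47. Id1, a transcriptional target of BMP signalling, was 2.23-fold lower (1.58 to 3.19) on 48 against 114 counts, and 11 of 14 BMP response genes had lower values, with a median of -0.24. The only named gene upward was Thap3, 2.52-fold higher (1.62 to 4.0) on 71 against 30 counts; the mitochondrial tRNA gene TrnH was 2.11-fold lower (1.28 to 3.57) on 24 against 54 counts.

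Other lists lay close to 0 in that comparison. Cell cycle genes had a median of 0.07 with 31 of 38 members above 0, collagens and fibrous matrix 0.06, interferon genes 0.02 with 21 of 38 above 0, and endoplasmic reticulum chaperones 0.02, all above the random band. Hypoxia and glycolysis (-0.11), oxidative stress (-0.10) and histone genes (-0.17) lay below it. The size rule gave 114 genes higher and 133 lower against 202.52 from sampling alone and 229 at most. With at least 30 counts it gave 2 (Thap3, and Gm12404, chosen after its values were seen) and 10, against 0.38 on average and 4 at most, and on TMM-scaled CPM 8 and 15, with 34.8% upward in place of 46.2%.

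**Figure D2:**
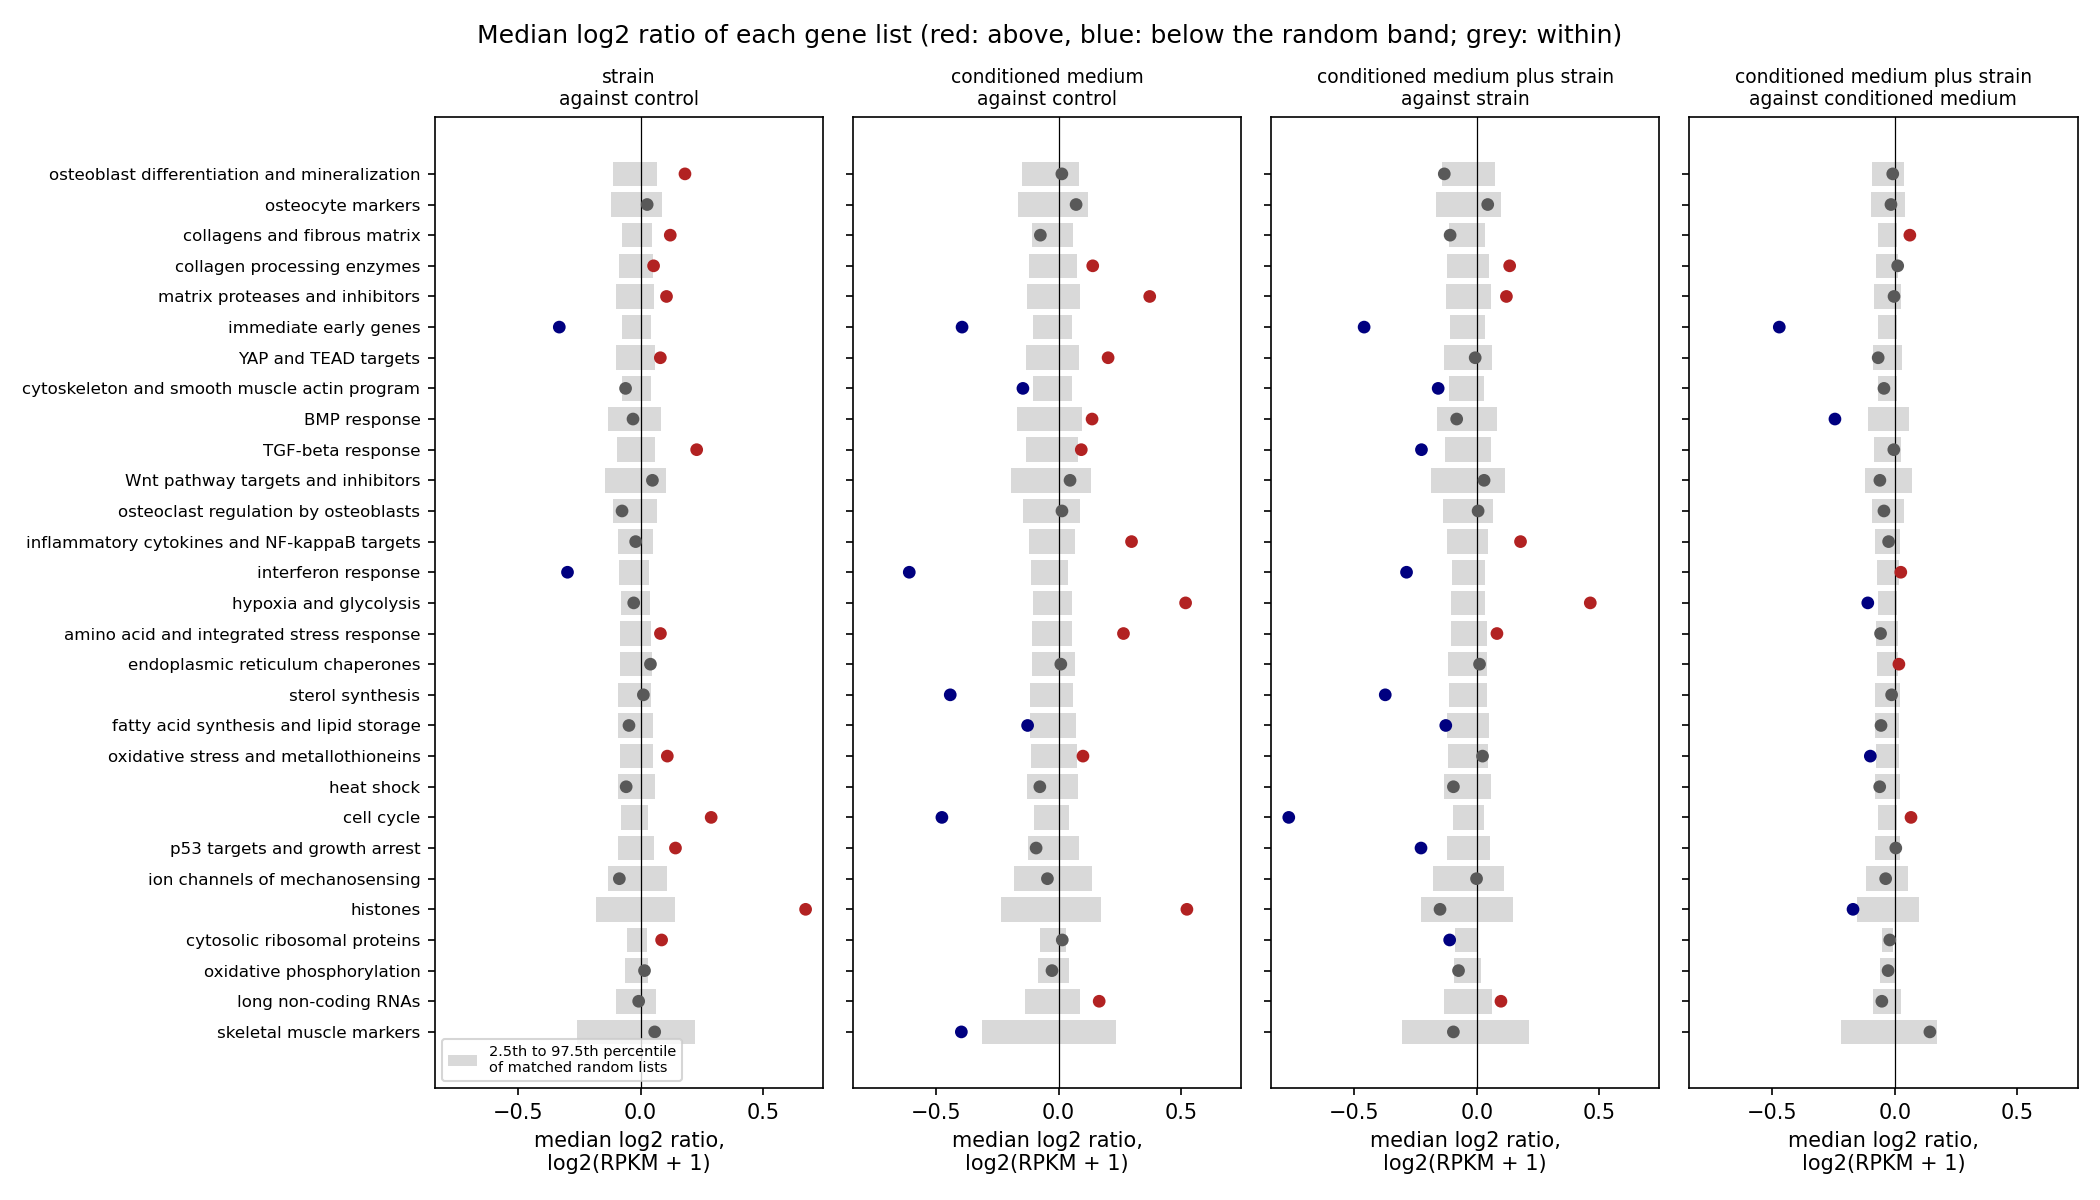
Median log2 ratio of each of the 29 gene lists with at least 5 expressed members, 1 point per list and 1 panel per comparison; grey bars span the central 95% of 10000 matched random lists. Cell cycle genes lie at 0.29, -0.48, -0.77 and 0.07 from the left panel to the right, and immediate early genes lie below the band in each panel.

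Conditioned medium plus strain against control does not depend on which single treatment is which. Fosb was 10.9-fold lower (10.1 to 11.9) with both treatments, Fos 5.77-fold (5.49 to 6.07), Egr3 5.68-fold (4.58 to 7.11), Klf2 5.43-fold (4.46 to 6.66) and Nr4a1 4.74-fold (4.24 to 5.32). In the immediate early list 12 of 26 members met the size rule downward and Fosl1 alone met it upward, with a median of -0.82. Mmp13 was 16.3-fold higher (13.9 to 19.2), Lcn2 14.5-fold (9.20 to 24.1), Spp1 2.79-fold (2.75 to 2.83) and Postn 2.18-fold lower (2.16 to 2.20). The transcriptional repressor gene Hes1 was 3.62-fold lower (2.80 to 4.71) and Zfp36, an mRNA-decay factor gene, 2.92-fold lower (2.68 to 3.17). List medians were -0.60 for interferon genes, -0.43 for sterol synthesis, -0.39 for the cell cycle and 0.42 for hypoxia and glycolysis. The size rule gave 176 genes higher and 179 lower, against 201.39 from sampling alone and 224 at most. With at least 30 counts it gave 76 and 34, against 0.45 on average and 2 at most, and on TMM-scaled CPM 138 and 59, with 70.1% upward in place of 49.6%.

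The 9 osteoblast genes fixed beforehand ranged from abundant to not detected. The transcription factor gene Runx2 had 16.3 RPKM in the control, 14.3 with strain and 12.3 in each conditioned-medium library, a fold of 1.33 lower (1.23 to 1.43) for conditioned medium against control. Sp7 (osterix) had 3.32, 3.18, 2.17 and 1.80 RPKM in the control, strain, conditioned-medium and combined libraries. Col1a1, the type I collagen gene, had 484, 587, 460 and 484 RPKM, and Tnfrsf11b (osteoprotegerin) 53.2, 46.6, 61.5 and 59.8. Alpl (alkaline phosphatase) lay between 0.647 and 0.882 RPKM, on 25 to 32 counts, and its interval included 1 in every comparison, with ratios of 0.994 (0.586 to 1.68) for strain against control and 1.11 (0.654 to 1.87) for conditioned medium plus strain against strain. Bglap (osteocalcin) had 1 to 5 counts, at which its differences were not detectable. Ibsp had 12 counts in the conditioned-medium library against 3 in the control, a ratio of 4.13 (1.11 to 22.8), and 3 with both treatments. Tnfsf11 (RANKL) had 0 counts in every library; 3 counts, the limit that a count of 0 allows, would be 0.122 to 0.134 RPKM at its length of 2235 bases. Of the mineralization list, Ank was 2.17-fold lower (2.0 to 2.36) with conditioned medium plus strain than with strain.

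The conditioned-medium responses with and without strain, which share no library, were correlated across 12283 genes with a mean RPKM of at least 1 (r = 0.39, rho = 0.43). Of these genes 58 met the size rule upward in both, where independent lists would share 1.23, and 25 downward, against 0.887, while 30 went opposite ways. For the 30 no independent number was computed, and such numbers assume that all genes pass the rule equally readily. Mmp13, Lcn2, Hp, Saa3, Kcnj15, Il4ra, Il6 and Nos2 were among the 58, and Otor, S100b, Egr3, Hes1, Olfm2 and Ccnb2 among the 25. Small RNA genes were a minority of the 58, among them Mir1949 and Snord49b. They made up most of the 25, among them Mir30a and Snord55, so the downward overlap was mainly one of small RNAs. With a mean RPKM of at least 20, r was 0.79 over 3390 genes. Of these, 24 met the size rule upward in both, 2 downward, and 0 went opposite ways. Genes are not independent replicates, and no p-value was computed.

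For the strain responses with and without conditioned medium, r was -0.02 and rho 0.086 over the same genes, and r turned positive with higher expression minimums, at 0.11 for a mean RPKM of at least 5. Fos, Fosb and Klf2 met the size rule downward in both; the other 17 genes that met it the same way in both (6 upward and 11 downward) were annotated as small RNAs or tRNA, and 27 genes went opposite ways. With a mean RPKM of at least 20, r was 0.24, and 0.13 without the immediate early genes and 3 genes with ribosomal RNA-like signal. The difference between the strain responses was past 1 on the log2 scale for 1 named gene upward, Thap3 (1.15), and 13 downward, among them Dmp1 (-1.87), Rpph1 (-1.63), Id1 (-1.24), TrnG (-1.22) and Il1rl1 (-1.14). Dmp1 stood at 5.30 RPKM with conditioned medium and 5.29 with conditioned medium plus strain, and Il1rl1 at 5.47 in the control against 14.5, 14.3 and 15.7 in the strain, conditioned-medium and combined libraries.

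**Figure D3:**
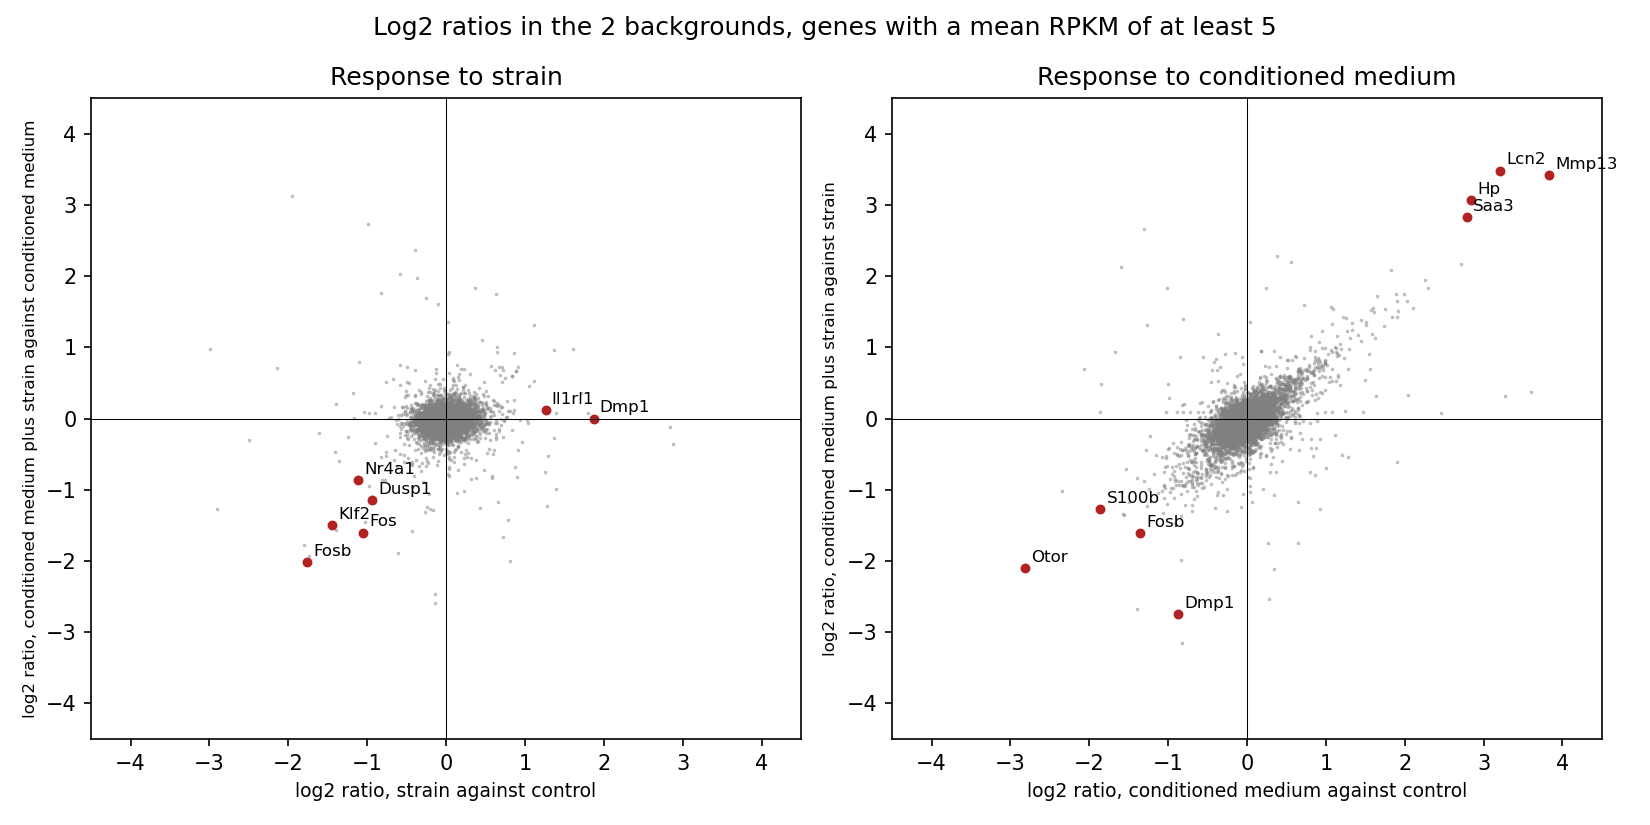
Log2 ratio of each gene with a mean RPKM of at least 5, 1 point per gene and no error bars: left, strain against control (x axis) and conditioned medium plus strain against conditioned medium (y axis); right, conditioned medium against control (x axis) and conditioned medium plus strain against strain (y axis). Across these 8628 genes r was 0.11 for strain and 0.62 for conditioned medium.

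Among lncRNA genes, 8 were higher and 9 lower by the size rule for strain against control, 12 and 5 for conditioned medium against control, 10 and 17 for conditioned medium plus strain against strain, and 7 and 11 for conditioned medium plus strain against conditioned medium; no sampling level was computed for them. With at least 30 counts, none met the rule for strain against control, and C430002N11Rik, Gm13293 and Gm33916 were higher both for conditioned medium against control and for conditioned medium plus strain against strain. Gm34921 and Lockd were lower for conditioned medium plus strain against strain, and for conditioned medium plus strain against conditioned medium Gm12404 was higher and 2500002B13Rik lower. Gm34921 overlaps Dusp6 on the opposite strand, also lower in that comparison, and Gm12404 overlaps Fam219a, so with the strand setting unknown their reads cannot be assigned with certainty. These lncRNA genes were chosen after their values were seen.

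Of the marker lists of other cell types, few members reached a mean of 1 RPKM, but some of these were well expressed. They were Sox9 and Col2a1 of 16 chondrocyte markers, with Sox9 at 34.3 RPKM in its highest library, and Dgat2, Lipe and Pnpla2 of 16 adipocyte markers, with Pnpla2 at 13.8. Of 15 skeletal muscle markers Des, Acta1, Mylpf, Tnni1 and Tnnc1 did so, with Tnnc1 at 33.3, of 16 macrophage and blood markers Lyz2, Lyz1, Cd14 and Cd74, with Lyz2 at 30.7, and of 13 endothelial markers Flt1, at 7.47. No epithelial marker did, the highest value being 1.14 for Krt14. Lists of osteocyte markers, Wnt targets, osteoclast regulators, heat shock genes, mechanosensing channels and oxidative phosphorylation stayed inside the random band in each of the 4 planned comparisons. The share of counts on Rn18s-rs5, a gene with ribosomal RNA-like signal, was 1.52% in the control (1.51 to 1.53, Clopper-Pearson), 2.80% with strain (2.79 to 2.81), 2.12% with conditioned medium (2.11 to 2.12) and 3.36% with both (3.35 to 3.37). It was thus highest in the library with both treatments, where Fos (84.9 RPKM) and Fosb (15.0 RPKM) were lowest. Of 28 symbols listed for mitochondrially encoded genes, with no tRNA genes among them, only mt-Rnr1 and mt-Rnr2 were present. They held 0.0868% to 0.120% and 0.359% to 0.506% of counts. The listed symbols of protein-coding genes were absent from the deposited values, so mitochondrial messenger RNAs could not be analysed.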

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

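Gene lists are given here where the response to one treatment lay above the random band in one background and below it in the other; with 1 library per group, none of these differences was tested, and no test was chosen after the result was seen for them.

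Interferon-response genes had a median log2 ratio of -0.30 for strain in ordinary medium (percentile 0) and 0.02 in conditioned medium (percentile 98.88), a difference of 0.32 that was not tested. Ifit1 had 36.1 RPKM in the control, 22.4 with strain, 11.8 with conditioned medium and 13.4 with both, and in conditioned medium 21 of 38 members lay above 0 and 17 below.

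Oxidative stress and metallothionein genes had a median of 0.11 for strain in ordinary medium (percentile 99.98) and -0.10 in conditioned medium (percentile 0.17), a difference of -0.21 that was not tested. Mt2 stood at 167 and 222 RPKM without and with strain in ordinary medium and at 723 and 655 in conditioned medium.

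Histone genes had a median of 0.67 for strain in ordinary medium (percentile 100) and -0.17 in conditioned medium (percentile 1.4), a difference of -0.84 that was not tested. The list had 7 expressed members, most on few counts. In the control, strain, conditioned-medium and combined libraries, Hist1h1b had 11, 28, 28 and 12 counts and Hist1h2ac 7, 17, 15 and 5. On more counts, Hist1h1c had 564, 760, 789 and 719 and Hist1h2bc 253, 277, 249 and 194. Their log2 ratios for strain were 0.46 and 0.16 in ordinary medium and -0.04 and -0.26 in conditioned medium. For strain in conditioned medium 2 of the 7 members lay above 0 and 5 below.

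TGF-beta response genes had a median of 0.09 for conditioned medium without strain (percentile 98.47) and -0.23 with strain (percentile 0.01), a difference of -0.32 that was not tested. Tgfbi had 10.6 RPKM in the strain library against 5.81, 5.96 and 6.08 in the control, conditioned-medium and combined libraries, and Skil 10.1 against 6.29, 6.77 and 7.07.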

How the results depend on the processing

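The minimum of 30 counts, the correlations without immediate early and ribosomal RNA-like genes, the library totals without the latter, and the comparison of both treatments with control were tests chosen only after the result was seen; the other alternatives were set before the data were examined. Counts of genes past the size rule depended on how genes with low values were treated, and are given as higher and lower for strain against control, conditioned medium against control, conditioned medium plus strain against strain, against conditioned medium, and against control, in that order. With a pseudocount of 0.1 they were 173 and 229, 284 and 272, 276 and 282, 190 higher (the lower count stayed within 1.5 times), and 284 and 312. With a pseudocount of 5 they were 7 and 19, 57 and 25, 41 and 23, 11 and 18, and 55 and 36. A minimum of 5 RPKM in the higher library gave 26 and 37, 99 and 66, 68 and 62, 24 and 42, and 90 and 72. With predicted-gene, pseudogene and small RNA names left out they were 22 and 7, 87 and 33, 60 and 47, 11 and 17, and 81 and 36. Of the 243 genes past the rule for strain against control, 15 were protein-coding and 17 lncRNA. TMM-scaled CPM gave 31 and 16, 135 and 55, 97 and 76, 8 and 15, and 138 and 59. At least 30 counts gave 9 and 5, 80 and 32, 53 and 35, 2 and 10, and 76 and 34. Fewer genes entered under the minimums and the name rule, and the pseudocount acts on low values by construction. The TMM factors shifted log2 ratios by 0.02 to 0.07. Median-of-ratios factors shifted them by 0.03 to 0.07 and left all 10 counts within 1.5 times. This argues against the factors themselves as the cause of the TMM-scaled CPM counts. CPM also drops gene length and puts the minimum and pseudocount on another scale, and the part of these was not tested. Leaving out the filter moved nothing, because no gene under 1 RPKM can reach the size rule at a pseudocount of 1, so it says nothing on stability. The correlation of the strain responses, -0.02, was -0.10 with a pseudocount of 0.1 and turned positive at a mean of at least 5 RPKM (0.11), at 20 RPKM (0.24) and as Spearman's rho (0.086); that of the conditioned-medium responses, 0.39, was 0.17, 0.62, 0.79 and 0.43, and the cause was not tested. Without the immediate early and ribosomal RNA-like genes they were -0.04 and 0.39. The skeletal muscle list for conditioned medium against control went from -0.40 to 0.91 with members at a mean of at least 5 RPKM, where fewer members enter. Of the other list medians under an alternative, 412 changed by less than the distance from the middle to the edge of their random band. The remaining 22 moved further. Among the 412 and the 22, 26 and 7 changed sign, all of lists inside the band. Of the ratios of named genes 282 stayed within their intervals and 46 moved, and the sign changed for Alpl (strain against control), Spp1 (both treatments against conditioned medium) and Col1a1 (both treatments against control), each near 0, under median-of-ratios scaling. No replicate could be left out and no replicated count test was run, with 1 library per group. No paired analysis was possible because the labels give no shared replicate and each group is 1 library. Depth limits genes with few counts: sampling of reads alone brought 200.91 to 212 genes past the size rule on average, and 0.36 to 0.45 with at least 30 counts.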

Other observations

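Of the tests below, that of the STAT3-linked list was written before its members' values were seen, though the idea came from these data. The median-of-ratios scaling and the count of genes meeting the size rule in both comparisons were set before the data were examined, but the use of that scaling as a test of the immediate early genes, like the remaining tests, was chosen only after the result was seen.

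Further genes, chosen after their values were seen, extended the account of the conditioned-medium libraries. Fth1, the ferritin heavy chain gene, had 3095 RPKM in the control and 3171 with strain, against 7065 with conditioned medium and 6248 with both, while the light chain gene Ftl1 was 1.04-fold higher for conditioned medium against control. Sod2, the mitochondrial superoxide dismutase gene, was 2.76-fold higher with conditioned medium than in the control and 2.64-fold with conditioned medium plus strain than with strain, and Clu (clusterin) 3.70-fold and 3.16-fold. The proliferation marker Mki67 had 45.4 RPKM in the control, 54.8 with strain, 26.5 with conditioned medium and 29.3 with both, and Top2a 52.5, 65.4, 32.0 and 33.1. Of 38 cell cycle genes, 31 had higher values with strain in both media.

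Rn18s-rs5 and LOC101056014, both with ribosomal RNA-like signal, took larger shares of counts in the strained libraries. Their ratio differed by at most 0.00711 on the log2 scale between any libraries, as a single ribosomal RNA source would give, whereas that of Lars2 to Rn18s-rs5 differed by 0.273. Leaving both and Lars2 out of the totals raised the ratios of all other genes for strain against control by 0.03 on the log2 scale, and moved the median over expressed genes from -0.026 to -0.0020. Incomplete removal of ribosomal RNA could vary between single preparations, and was not tested apart from strain. No biological explanation was tested.

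Most immediate early genes had lower values in the strained library in both media. Sampling of reads is argued against, since 18 of 26 members in ordinary medium and 21 in conditioned medium had intervals wholly below 1, and so is scaling, since the medians were -0.30 and -0.44 after median-of-ratios scaling. These transcripts are induced within minutes, so the time between the last strain or medium change and harvest, or handling, may set their level. With 1 library per group this cannot be told apart from an effect of strain, which stays open as a hypothesis. Lower values of this list were not particular to strain. Its median was -0.39 for conditioned medium against control and -0.46 for conditioned medium plus strain against strain.

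Most genes of the inflammatory list and of the hypoxia and glycolysis list had higher values in both conditioned-medium libraries. Sampling of reads is argued against: 32 of 49 expressed members of the inflammatory and hypoxia lists had intervals wholly above 1 in both comparisons and 0 wholly below, against 0.0306 by chance. Over all genes, the number meeting the size rule upward in both comparisons was 47.3 times that of independent lists. This multiple cannot decide on sampling, because genes with few counts pass the rule more readily than independent lists allow. The strain responses shared 6 upward genes against 0.283 for independent lists, all of them small RNAs or tRNA. Human RNA carried over from PC-3 cells cannot be told apart, because the 14 epithelial markers held 36 counts in the conditioned-medium libraries and 61 in the others, a ratio of shares of 0.620 (0.399 to 0.952), with none at a mean of 1 RPKM. A candidate explanation is interleukin 6 family signalling through STAT3 in the osteoblasts: 11 further STAT3-linked genes had medians of 0.21 (percentile 99.89) without strain and 0.14 (percentile 99.43) with it. Of the 29 fixed lists, 11 also stood above the band without strain and 6 with it, the long non-coding RNAs (0.17 and 0.10) among both. A place above the band therefore does little to single out STAT3. The medians of the STAT3-linked genes were small, and members ranged from Hif1a (0.65 and 0.69) to Ccnd1 (-0.18 and -0.20). Signalling through STAT3 thus remains a hypothesis from these libraries.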
